A study of Homo sapiens with 12 samples.

How the data were processed

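The data were bulk RNA-seq profiles of SNU638, an established human gastric cancer cell line. Per the series' design text, the cells were infected with packaged lentivirus, and stable lines were selected with puromycin. Per the sample titles, 1 line carried a control hairpin and 3 lines carried different short hairpin RNAs against SKA2, with 3 libraries per line and 12 libraries in all. Groups and replicate numbers were taken from the titles. The labels do not say whether the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

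Per the labels' protocols, RNA was extracted with Trizol, polyadenylated mRNA was enriched on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers before sequencing on the BGISEQ-500 platform. The protocol names no step that marks the strand, so reads of overlapping genes on opposite strands cannot be told apart. Random priming of fragmented mRNA spreads reads along a transcript, so a long transcript gives more reads than a short one at the same number of molecules. Per the submitters' processing notes, HISAT, Bowtie2, RSEM and DESeq2 were used with genome build GRCh38.p13. The role, order and version of each tool, and any filter on genes, are not given in the sources used here.

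The authors deposited 1 table of 17303 genes with Entrez identifiers and symbols, holding for each library an expected count, an FPKM and a TPM per the file headers. The deposited read count columns hold expected counts, which share ambiguous reads between genes, and are given to at most 2 decimals. Of the values per library 84.0% to 86.0% were exactly whole, zeros included, and 81.8% to 83.6% of those above 0. The deposited FPKM values are scaled by the authors to transcript length and to the number of reads. The deposited TPM values are scaled by the authors to sum to the same total in each library. A further 15 columns of the authors' group averages were not used. Gene identity was taken from the deposited table, and 17084 Entrez identifiers matched the GENCODE v29 annotation of GRCh38, from which positions, transcript lengths and GC content were taken.

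Expected counts were rounded to whole numbers and tested with edgeR (4.0.16, in R 4.3.3). Genes were kept by the tool's expression filter on the 4 groups, which left 12868 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 factor for the hairpin was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.111. Each hairpin was compared with the control, the mean of the 3 hairpins was compared with the control, and the hairpins were compared with each other. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes, marked SE, are the absolute change divided by the square root of edgeR's quasi-likelihood F statistic. They stand in for standard errors and can be too small for genes with few counts in a group. CPM are counts scaled to the library total after TMM, and their errors are SDs over 3 libraries. Summed marker levels, the CPM of PPAN-P2RY11 and the ratios from floors or counting intervals used the unadjusted library total. Each hairpin has its own level in the fit, so the SE and p of the mean contrast leave out the spread between hairpins. For single values, exact two-sided permutation tests were run, which cannot go below p = 0.1 for 3 libraries against 3.

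Gene groups were tested with limma's camera (3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists within each comparison. The 41 lists covered pathways, complexes, the chromosomal neighbours of SKA2 and markers of other cell types. Of these, 36 had at least 5 tested members. The groups, the tests, the processing alternatives, the lists and the rule for named genes were fixed before the data were examined.

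Genes were named by this rule. SKA2, SKA1, SKA3 and PRR11 were always named. For the mean of the hairpins, the 12 largest rises and the 12 largest falls were named among genes with a symbol, at least 1 CPM on average over the 12 libraries, a call in the same direction with each of the 3 hairpins, and all 9 knockdown libraries on 1 side of all 3 control libraries. Chance gives such a separation for 0.909% of genes. This share, like the one given below, treats the libraries as exchangeable, although they come from 4 lines. With the lines kept whole, no share below 0.25 is possible. For each hairpin against the control, the 5 largest changes in each direction were named among called genes with at least 1 CPM over the 6 libraries and no overlap between the groups, a separation that chance gives for 10% of genes. For each pair of hairpins the 4 largest in each direction were named by the same rule, and for each list described up to 4 members with the smallest adjusted p were named. Of the genes that meet this rule, 1 is not reported here. Where a group had 0 counts of a gene, the fold was computed against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only.

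The processing alternatives were RLE scaling, library size alone, no filter and a stricter filter (1 CPM in at least 3 libraries and a mean of 50 counts). They also covered DESeq2 (1.42.0), limma-voom, limma on log2(TPM + 1), a threshold of a 2-fold change, an adjusted p under 0.01, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. For lists, the alternatives were camera with an estimated correlation, fry, and lists without genes that stand in more than 1 list. After the data had been seen, 3 alternatives were added, because libraries differed in how counts depended on transcript length. The first gave each library an offset fitted by natural splines with 5 degrees of freedom on log2 effective length and on GC content. The second used each library's length slope as a covariate. The third left out the first control and first hairpin 3 libraries together. Effective length was computed from the deposited expected counts and FPKM, and it correlated with the annotated length of the longest transcript at a Spearman rho of 0.886 across genes. Length and GC content were known for 12771 of the tested genes (99.2%).

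The titles give the replicates of every line the numbers 1 to 3. Deviations from the group means of libraries with the same number correlated between the control and hairpin 3 lines in each of the 3 pairs (Pearson r across genes of 0.73, 0.17 and 0.60). None of the other 15 pairs of same-numbered libraries exceeded 0.1. The numbers were therefore read from the data as a possible pairing of the control and hairpin 3 libraries, and as only a name elsewhere. The deviations of a line sum to 0 over its 3 libraries, so the 3 correlations are not independent of each other. This pair of lines was singled out by these same values. Both lines also had the same order of length slopes, so a match of order by chance is not excluded.

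The edgeR test was tested for hairpin 1 and for the mean of the hairpins on simulated counts drawn with the means, dispersions and library sizes of the 12868 genes, with 200 genes changed. For hairpin 1 against the control, 62.7% of the 1.5-fold changes, 86.6% of the 2-fold changes and 100% of the 4-fold changes were recovered, and 0.071% of unchanged genes were called. For the mean of the hairpins these shares were 74.6%, 89.6% and 100%, with 0.0395% of unchanged genes called. When the libraries' own length and GC trends were added to the simulated counts, 23.6% of unchanged genes were called for hairpin 1 and 38.0% for the mean. With the offsets in the model, these shares fell back to 0.071% and 0.0868%. Each gene was drawn with the same dispersion in all lines. In the data, the chi-square per degree of freedom between 2 libraries of a line was 6.62 to 51.0 in the control line. It was 1.68 to 1.97 with hairpin 1, 2.24 to 5.35 with hairpin 2 and 2.92 to 46.8 with hairpin 3. The simulation therefore cannot show the error rates when lines differ in spread. In a simulation of the 36 lists for the mean of the hairpins with 1 list lowered, camera called that list and 0 of the others. Genes were drawn independently there, so this cannot show false calls that come from correlated genes.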

Results

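Gene expression was profiled by RNA-seq in 12 libraries of SNU638, a human gastric cancer cell line. The libraries came from 4 stable lines made with lentivirus and puromycin, with 3 libraries each. The first line carried a control hairpin, and the others carried SKA2 hairpin 1, hairpin 2 or hairpin 3. Each library held between 1.47e+07 and 1.67e+07 counts over 17303 genes, and 12868 genes passed the expression filter and were tested. The series set out to find the genes whose expression is regulated by SKA2 in gastric cancer cells. SKA2 (Entrez 348235) encodes a subunit of the spindle and kinetochore associated complex, which holds chromosomes to spindle microtubules. It lies on chromosome 17 from 59109951 to 59155269 on the minus strand (GRCh38, GENCODE v29), a span of 45319 bp.

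SKA2 was lower in every knockdown library than in every control library. The control libraries held 126, 119 and 117 CPM, a mean of 120 ± 4.84 (SD, n = 3). The level was 26.0, 22.3 and 23.7 CPM with hairpin 1, 23.3, 25.3 and 27.2 CPM with hairpin 2, and 24.9, 26.9 and 28.0 CPM with hairpin 3. These means were 80.1%, 79.03% and 77.9% below the control mean. Between 1831 and 1989 reads of SKA2 were counted per control library and between 344 and 443 per knockdown library. The log2 fold changes were -2.33, -2.25 and -2.18 (SE 0.08 each), with adjusted p of 6.09e-09, 1.98e-09 and 8.24e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact two-sided permutation test of the 9 knockdown libraries against the 3 control libraries gave p = 0.00455 (adjusted p = 0.0182 over 4 comparisons). It treats the libraries as exchangeable, although they come from 4 lines, and with the lines kept whole no share below 0.25 is possible. For 1 hairpin against the control the same exact test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The differences in SKA2 between hairpins (2 and 1, 3 and 1, 3 and 2) were 0.075, 0.15 and 0.075 on the log2 scale, and none passed edgeR's test (adjusted p = 0.473, 0.243 and 0.452).

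The partners of SKA2 in its complex did not move alike. SKA1 (Entrez 220134) fell with each hairpin, with log2 fold changes of -0.91 ± 0.07, -2.07 ± 0.07 and -0.68 ± 0.07 for hairpins 1, 2 and 3 (SE, n = 3 per line). SKA3 (Entrez 221150) fell with hairpin 2 (-2.06 ± 0.07) and by less with hairpin 1 (-0.24 ± 0.06), and its log2 fold change with hairpin 3 was -0.02 (adjusted p = 0.827 in edgeR). PRR11 (Entrez 55771), a cell-cycle gene, lies head to head with SKA2 on the plus strand, at 59155499 to 59204705, with 229 bp between the starts of the genes. It fell by 0.55 ± 0.16 with hairpin 2 (adjusted p = 0.00678), while its log2 fold changes with hairpins 1 and 3 were -0.03 and 0.03 (adjusted p = 0.89 and 0.889 in edgeR). Its mean over the hairpins was -0.18 ± 0.12 (adjusted p = 0.208 in edgeR), and this gained a call with length and GC offsets (-0.54), with the length slope as a covariate (-0.74) and without the first hairpin 3 library (-0.26). Of the 19 tested genes around SKA2 on 17q22-q23, fixed as a list, 9, 9 and 8 were higher and 2, 6 and 2 lower with hairpins 1, 2 and 3. The same numbers were called when adjusted over the list alone, and camera did not call the list with any hairpin (adjusted p = 0.248, 0.311 and 0.0637).

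**Figure D1:**
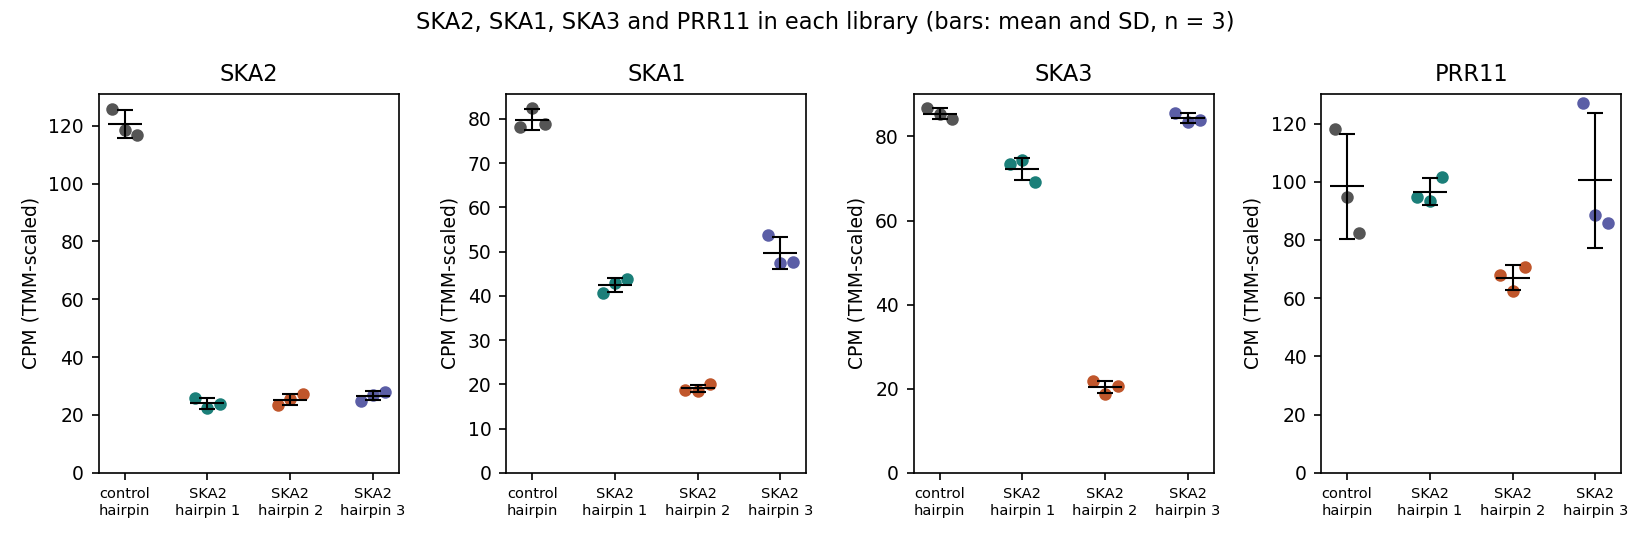
CPM of SKA2, SKA1, SKA3 and PRR11 in each of the 12 libraries (points), by line, with bars for the mean and SD (n = 3) and linear axes that start at 0. SKA2 lies between 117 and 126 CPM in the control libraries and between 22.3 and 28.0 CPM in the knockdown libraries, while SKA3 stays near the control level with hairpin 3.

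Which genes changed on average over the 3 hairpins was asked next. The SEs of this mean contrast hold the spread between libraries of a line and leave out the spread between hairpins. TRIB3 is a pseudokinase induced by the transcription factor ATF4. It went from 479 CPM in the controls to 23.5, 37.4 and 18.3 CPM with hairpins 1, 2 and 3. Its mean log2 fold change was -4.25 ± 0.09 (SE, 9 libraries of 3 lines against 3 of the control line). INHBE, an activin subunit gene (-4.77 ± 0.16), and ADM2, which encodes a peptide hormone (-4.12 ± 0.10), fell with it. So did the chemokine gene CCL20 (-4.07 ± 0.13) and IL1RL1, the interleukin-33 receptor gene (-3.96 ± 0.13). CHAC1, which degrades glutathione, fell by 3.54 ± 0.11, and DDIT4, an inhibitor of mTORC1, fell by 3.42 ± 0.09, from 226 CPM to 27.4, 19.6 and 17.6 CPM. UPP1, uridine phosphorylase (-3.40 ± 0.10), the glycine transporter gene SLC6A9 (-3.32 ± 0.11), NUPR1, a stress-induced nuclear protein gene (-3.90 ± 0.31), and MIOX, the inositol oxygenase gene (-3.81 ± 0.45), were lower as well. RAET1L, a ligand gene of an immune receptor, fell by 3.55 ± 0.26, but this value is uncertain because it is nearly identical to ULBP2.

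Among genes with at least 1 CPM on average over the 12 libraries, the largest rise was that of BMF, a pro-apoptotic BH3-only gene, from 2.21 CPM in the controls to 10.6, 133 and 15.6 CPM with hairpins 1, 2 and 3 (mean log2 fold change 3.66 ± 0.10). THSD7A rose by 3.30 ± 0.38 and the interferon-induced GTPase gene GBP2 by 3.24 ± 0.40. Similar changes with the 3 hairpins were measured for SCG2, a secretory granule protein gene (13.2, 11.8 and 12.5 CPM against 1.54 in the controls, 3.02 ± 0.15), and for MEF2C, a transcription factor gene (2.82, 2.82 and 2.49 CPM against 0.341, 2.96 ± 0.26). SMAD6, an inhibitor of BMP signalling, rose by 2.76 ± 0.16. DNAAF1 (2.91 ± 0.41), ZNF608 (2.84 ± 0.19), SAMD11 (2.80 ± 0.23) and CCDC170 (2.77 ± 0.18) rose as well. SLC2A14 rose by 2.83 ± 0.38, which is uncertain because it is nearly identical to SLC2A3. For each of these genes the adjusted p of the mean contrast was at most 8.5e-05 in edgeR. That each lay on 1 side of all 3 control libraries in all 9 knockdown libraries was a condition for naming it. Of 12868 tested genes, 1397 in the higher and 1642 in the lower direction met the conditions for naming before the largest were taken.

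Among the gene lists, the ATF4 targets and amino acid response genes moved most. Of 31 tested members, 30 were lower and 1 was higher in the mean of the hairpins, with the same numbers adjusted over the list alone, and the median log2 fold change was -1.50 (camera adjusted p = 7.53e-16, and 0.0253 with an estimated correlation). ASNS, which makes asparagine (-3.08 ± 0.05), the stress sensor gene SESN2 (-3.16 ± 0.06) and the amino acid transporter gene SLC7A5 (-2.02 ± 0.04) were among those with the smallest adjusted p. The member that rose was DDR2, a collagen receptor kinase and not an amino acid response gene, at 1.68 ± 0.19. It was named after its value was seen. Kinetochore and centromere genes were also lower in the mean (23 of 33 lower, 3 higher, also over the list alone; median -0.48; camera adjusted p = 0.000423, and 0.0253 with an estimated correlation). Their median was -1.32 with hairpin 2, while with hairpins 1 and 3 it was -0.077 and -0.019 (7 and 10 higher, 16 and 8 lower, and 7 and 10 higher, 16 and 9 lower over the list alone), and camera did not call the list with either (adjusted p = 0.342 and 0.878). SKA1, SKA3, CENPU and HJURP, the last a chaperone of centromeric histone, had the smallest adjusted p of that list, with SKA3 at -0.77 ± 0.05, CENPU at -0.71 ± 0.05 and HJURP at -0.66 ± 0.05. The call of SKA3 was lost when the 9 knockdown libraries were fitted as 1 group (-0.53). DNA replication and S phase genes were lower in the mean too (27 of 45 lower, 3 higher, also over the list alone; median -0.27; camera adjusted p = 0.000314, and 0.0253 with an estimated correlation). Their median was -0.97 with hairpin 2, and 0.12 and -0.055 with hairpins 1 and 3 (18 and 13 higher, 12 and 12 lower, and 20 and 13 higher, 13 and 12 lower over the list alone), where camera did not call the list (adjusted p = 0.394 and 0.878). CDC45, part of the replicative helicase, was at -1.14 ± 0.06 and TYMS, thymidylate synthase, at -0.78 ± 0.05.

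**Figure D2:**
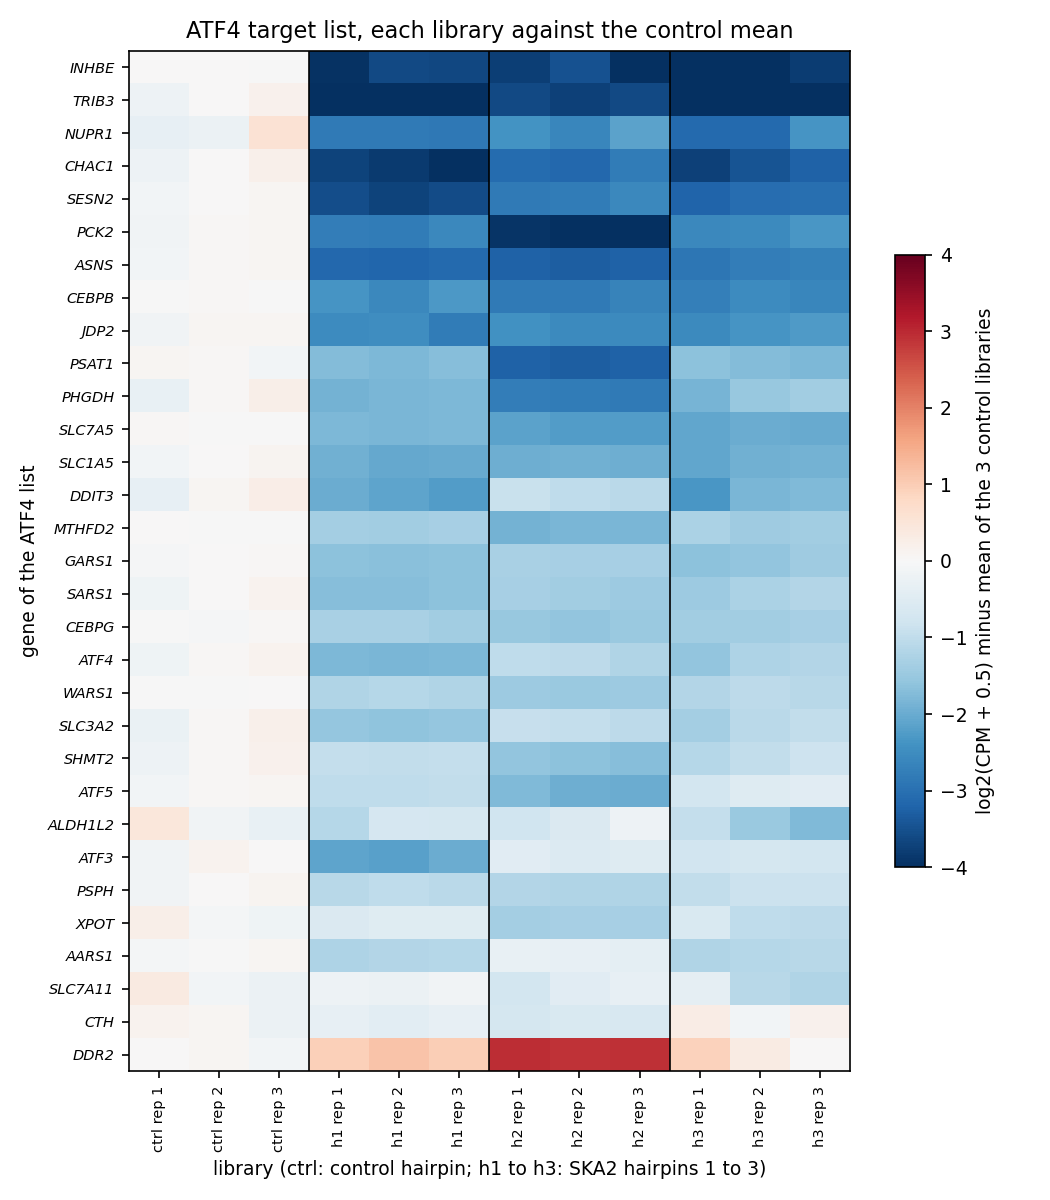
Log2 CPM (prior 0.5) minus the control mean for each tested member of the ATF4 and amino acid response list (vertical axis) in each of the 12 libraries (horizontal axis), on a colour scale that stops at -4 and 4. Of the 31 members, 30 were called lower in the mean of the hairpins and DDR2 was called higher.

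Another 11 lists were called by camera for the mean of the hairpins with the preset correlation and not with an estimated one. Those with a higher median were the type I interferon response (median 0.43, adjusted p = 0.0528 with an estimated correlation), heat shock genes (0.32, adjusted p = 0.333 with an estimated correlation), cholesterol genes (0.36, adjusted p = 0.108 with an estimated correlation) and replication-dependent histones (0.74, adjusted p = 0.0759 with an estimated correlation). Lower medians were found for G2/M genes (-0.22, adjusted p = 0.333 with an estimated correlation), NF-kB genes (-0.28, adjusted p = 0.248), ERK output genes (-0.70, adjusted p = 0.333), matrix and integrin genes (-0.26, adjusted p = 0.217) and MYC and nucleolar genes (-0.39, adjusted p = 0.333), each p with an estimated correlation. Cytosolic ribosomal protein genes (73 of 78 lower, 74 over the list alone, median -0.48) and respiratory chain genes (35 of 55 lower, also over the list alone, median -0.38) had adjusted p = 0.563 and 0.579 with an estimated correlation. The medians of these last lists turned to 0.15 and 0.10 with each library's length slope as a covariate. Without the first control library, the calls of the G2/M (-0.21), NF-kB (-0.23), heat shock (0.30), cholesterol (0.34), ERK (-0.54) and matrix (-0.19) lists were lost, and that of the NF-kB list also without the first hairpin 3 library (-0.29).

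The medians of these 11 lists with hairpins 1, 2 and 3, in that order, were -0.22, 1.08 and 0.35 for interferon, 0.15, -0.039 and 0.56 for heat shock, 0.33, 0.36 and 0.29 for cholesterol and 0.0013, 1.54 and 0.68 for histone genes. They were 0.15, -1.18 and 0.34 for G2/M, -0.78, 0.32 and -0.71 for NF-kB, -0.24, -0.84 and -0.28 for ERK output, -0.055, -0.67 and -0.17 for matrix and -0.30, -0.64 and -0.14 for MYC genes. For ribosomal protein genes they were -0.54, -0.77 and -0.11 and for respiratory chain genes -0.50, -0.49 and -0.19. With hairpin 1, 10 of 51 interferon genes were higher and 15 lower (10 and 14 adjusted over the list alone), and 0 of 16 histone genes higher and 1 lower (0 and 0 over the list alone). With hairpin 2, 14 of 26 NF-kB genes were higher and 7 lower (also over the list alone), and 9 of 19 heat shock genes higher and 8 lower (9 and 9 over the list alone). Camera did not call these 4 (adjusted p = 0.585, 0.985, 0.407 and 0.493). With hairpin 3, 0 of 78 ribosomal protein genes were lower and 1 higher (0 and 0 over the list alone), and 16 of 55 respiratory chain genes were lower and 3 higher (15 and 3 over the list alone). Camera called neither (adjusted p = 0.256 and 0.127), but both gained a call without the first control library (-0.27 and -0.30) or the third hairpin 3 library (-0.22 and -0.29). Calls were also gained with hairpin 1 for MYC genes without the first control library (-0.33) and for heat shock (0.21) and cholesterol genes (0.32) without the third. The same held for cholesterol genes with hairpin 2 without the third control library (0.39) and for ERK output genes with hairpin 3 without it (-0.35) or without the first hairpin 3 library (-0.28).

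In total 4339 genes were higher and 4608 lower in the mean contrast, 69.5% of those tested, and 871 and 684 of them changed at least 2-fold. Of the called genes 48.5% were higher with TMM scaling and 74.3% with limma on log2(TPM + 1), where the median of all genes shifted by 0.25. That alternative changes the scale, the test and the added offset together, and their parts in the share of calls were not separated. The test does not enter the median shift. TPM scaling divides by a library's FPKM sum, which was 600684 to 726871 in the control libraries. It was 541925 to 549567 with hairpin 1, 504100 to 539517 with hairpin 2 and 562401 to 673840 with hairpin 3. The lower sums with hairpins 1 and 2 raise all TPM values in those libraries. A fit with all 9 knockdown libraries as 1 group called 2518 genes higher and 2408 lower.

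Whether independent hairpins shared their changes was examined through genes called with each of the 3. This held for 1788 genes in the higher direction and 1930 in the lower, of which 247 and 268 changed at least 2-fold with every hairpin. Independent lists of these sizes would share 350 and 368 genes. In 20 simulations of unchanged groups against the same controls, 0 genes were shared. These held no length or GC trend and gave each gene the same dispersion in all lines. With each library's estimated trend added, a simulation chosen after the data had been seen, at most 1 gene was shared in the higher direction and 0 in the lower. The simulated spread was estimated from libraries that already held the trend, so adding the trend widened it further, which can hide calls. In the check of the edgeR test, an added trend led to calls of 23.6% of unchanged genes for hairpin 1 and 38.0% for the mean. The low sharing therefore cannot show that the trend creates no shared calls. Across genes, log2 fold changes correlated between hairpins 1 and 2 (Pearson r = 0.672), hairpins 1 and 3 (r = 0.853) and hairpins 2 and 3 (r = 0.599), where unchanged groups that shared the controls gave 0.495, 0.490 and 0.489. Genes are not independent replicates, so no p is given. The covariances were 0.524, 0.391 and 0.394 against 0.0229, 0.0228 and 0.0226 in the simulations without a trend. With the trend added, the simulated r were 0.896, 0.791 and 0.786 and the covariances 0.226, 0.118 and 0.144, so that the r of hairpins 1 and 2 and of hairpins 2 and 3 lay below the simulated values and the covariances above. For hairpins 1 and 3, 2539 genes were higher and 2596 lower with both (957 and 973 from independent lists), and 26 genes were called in opposite directions. That number was 734 for hairpins 1 and 2 (2793 and 2947 shared, 1485 and 1534 from independent lists) and 767 for hairpins 2 and 3 (1992 and 2152 shared, 1112 and 1166 from independent lists). The 3 control libraries are too few to be split, so part of the excess may come from the shared controls. Without the third control library 1147 genes were shared in the higher direction and without the second 1190. When each line in turn took the place of the control, 279 genes were shared for hairpin 1, 5151 for hairpin 2 and 274 for hairpin 3, against 3718 for the control line.

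What hairpin 1 changed by itself was compared with the control line. MYCT1 gave 2 reads over the 3 hairpin 1 libraries and 114 over the controls, a ratio of control to hairpin 1 of 53.04 (95% counting interval 14.4 to 443). KLHDC7B (log2 fold change -4.92 ± 0.54), ROBO4, a guidance receptor gene of endothelium (-4.49 ± 0.50), INHBE (-4.51 ± 0.22) and MCAM, a cell adhesion gene (-4.78 ± 0.88), were other large falls. The control libraries held 4.43, 24.6 and 37.0 CPM of MCAM, and its call was lost with the length slope as a covariate (-0.85). The largest rises among genes with at least 1 CPM on average were those of SLCO1C1, an organic anion transporter gene (3.78 ± 0.58), DNAAF1, a dynein assembly factor gene (3.36 ± 0.43), SCG2 (3.10 ± 0.17) and MEF2C (3.02 ± 0.29). The SLCO1C1 call was also lost with that covariate (1.51). ZBED6 rose by 3.35 ± 0.70, which is uncertain because it lies within ZC3H11A.

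Of the ATF4 and amino acid response genes 29 of 31 were lower with hairpin 1 and 1 was higher, also over the list alone, with a median of -1.76 (camera adjusted p = 1.03e-17, and 0.047 with an estimated correlation). The log2 fold changes were -4.35 ± 0.13 for TRIB3, -3.63 ± 0.09 for SESN2, -3.16 ± 0.07 for ASNS and -1.81 ± 0.06 for SLC7A5. ATF4 itself, named after its value was seen, was at -1.83 ± 0.11. Inflammatory genes regulated by NF-kB were lower as well, 19 of 26 against 2 higher (19 and 3 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 3.48e-05, and 0.047 with an estimated correlation). Among them the neutrophil chemokine genes CXCL3 and CXCL1 were at -2.62 ± 0.08 and -1.77 ± 0.09, CCL20 at -4.17 ± 0.18 and the cytokine gene LIF at -1.44 ± 0.05. Ribosomal protein genes were lower in 71 of 78 cases (77 adjusted over the list alone, median -0.54), with RPSA at -0.82 ± 0.15 and RPLP0 at -0.80 ± 0.15. Of 55 respiratory chain genes 39 were lower (also over the list alone, median -0.50). Both lists were called by camera (adjusted p = 5.31e-08 and 1.9e-05) but not with an estimated correlation (adjusted p = 0.559 for each), and their medians turned to 0.12 and 0.052 with the length slope as a covariate. Camera called 0 lists higher with hairpin 1, but 7 with length and GC offsets and 5 with that covariate.

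With hairpin 1, 4055 genes were higher and 4059 lower (63.1% of those tested), of which 909 and 606 changed at least 2-fold. The share of higher genes among the calls was 49.98%, and 78.9% with limma on log2(TPM + 1), where all genes shifted by a median of 0.29. With the length slope as a covariate 2522 genes were higher, of which 1654 were among the 4055, while 87 of the 4055 were called lower.

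The same comparison for hairpin 2 gave the most calls of the 3 hairpins. BMF rose by 5.91 ± 0.11 to 133 CPM and GBP2 by 5.19 ± 0.35. LRRTM3, a synaptic adhesion gene, gave 91 reads against 1 in the controls, a ratio of 99.3 (17.4 to 3965), and CALB2, which encodes calretinin, gave 96 reads against 3, a ratio of 34.9 (11.6 to 172). The growth factor gene IGF2 gave 3 reads with hairpin 2 and 307 in the controls, a ratio of control to hairpin 2 of 93.8 (31.8 to 457). MCAM fell by 6.13 ± 1.04, and its call was lost with the length slope as a covariate (-1.27). The other genes named by size share reads with longer transcripts and are uncertain. P2RY11 had 0 counts with hairpin 2, at least 340-fold lower than in the controls, while its readthrough transcript PPAN-P2RY11 held 12.8 CPM against 14.4. CEMP1, within AMDHD2, was at least 35.2-fold lower and EIF4EBP3, which overlaps ANKHD1-EIF4EBP3, at least 34.5-fold lower. PHOSPHO2-KLHL23, a readthrough of KLHL23, had 0 counts in the controls and was at least 79.6-fold higher. The calls of CEMP1 and EIF4EBP3 were lost with the length slope as a covariate (-3.05 and -4.05), and that of CEMP1 without the third control library (-7.09).

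Genes of cell division and DNA synthesis were lower with hairpin 2. Of 43 G2/M genes 37 were lower and 0 higher, with a median of -1.18 (camera adjusted p = 1.78e-11, and 0.0238 with an estimated correlation), among them the microtubule depolymerase gene KIF2C (-1.97 ± 0.07), the spindle genes DLGAP5 (-1.63 ± 0.07) and TPX2 (-1.45 ± 0.05) and the central spindle gene PRC1 (-1.61 ± 0.06). Kinetochore and centromere genes were lower in 29 of 33 cases and higher in 1, with a median of -1.32 (camera adjusted p = 1.46e-08, and 0.00226 with an estimated correlation), including CENPN (-1.88 ± 0.07) and HJURP (-1.58 ± 0.06). All 19 spindle checkpoint and chromosomal passenger genes were lower (median -0.89, camera adjusted p = 2.49e-05, and 0.0238 with an estimated correlation), with BIRC5, which encodes survivin, at -1.84 ± 0.11. Of 45 DNA replication genes 42 were lower (median -0.97, camera adjusted p = 8.09e-12, and 0.00114 with an estimated correlation), with CDC45 at -2.22 ± 0.09, TYMS at -1.83 ± 0.07 and the primase gene PRIM1 at -1.58 ± 0.07. Each of these 4 counts was the same adjusted over the list alone. The ATF4 list was lower as with hairpin 1 (29 of 31, 30 over the list alone, 1 higher; median -1.65; camera adjusted p = 1.78e-11, and 0.0304 with an estimated correlation), with the serine synthesis gene PSAT1 at -3.27 ± 0.07 and PCK2 at -4.15 ± 0.11.

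Interferon response genes were higher with hairpin 2 in 40 of 51 cases and lower in 2 (41 and 2 over the list alone), with a median of 1.08 (camera adjusted p = 4.16e-08, and 0.00646 with an estimated correlation). PARP14 rose by 2.34 ± 0.12, the antiviral gene IFIT3 by 1.99 ± 0.12, the transcription factor gene IRF1 by 1.79 ± 0.11 and PARP9 by 1.74 ± 0.09. Of 16 replication-dependent histone genes 14 were higher (also over the list alone), with a median of 1.54 (camera adjusted p = 8.96e-05, and 0.0238 with an estimated correlation). H2AC6 rose by 2.72 ± 0.19, H2BC5 by 2.10 ± 0.12 and the linker histone gene H1-2 by 2.08 ± 0.15. Most transcripts of these genes lack a poly(A) tail, so libraries made from polyadenylated RNA count few of them.

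A further 6 lists were lower with hairpin 2 only under the preset correlation. The summed markers of fibroblasts and of endothelium were below the lowest control level in the libraries of each hairpin (knockdown 19.7 to 29.5 and 14.4 to 34.3 CPM, control 46.4 to 51.6 and 35.5 to 50.4 CPM). Matrix and integrin genes (18 of 30 lower, 19 over the list alone, median -0.67, adjusted p = 0.0964 with an estimated correlation) included the collagenase gene MMP1 (-4.08 ± 0.14), the plasminogen activator gene PLAU (-2.78 ± 0.07) and its receptor gene PLAUR (-3.17 ± 0.12). ERK output genes (15 of 23 lower, also over the list alone, median -0.84, adjusted p = 0.252 with an estimated correlation) included DUSP6, a phosphatase of ERK (-1.98 ± 0.08), and ETV4 (-2.36 ± 0.14). Homologous recombination and Fanconi genes (15 of 28 lower and 4 higher, also over the list alone, median -0.61) had adjusted p = 0.473 with an estimated correlation, with FANCI at -1.99 ± 0.07. MYC and nucleolar genes (26 of 34 lower, also over the list alone, median -0.64) had adjusted p = 0.149 with an estimated correlation and were not called with length and GC offsets (-0.37). Ribosomal protein genes (77 of 78 lower, also over the list alone, median -0.77) and respiratory chain genes (39 of 55 lower, also over the list alone, median -0.49) had adjusted p = 0.543 and 0.644 with an estimated correlation. The calls of these last lists were lost with offsets (-0.32 and -0.16), and their medians turned to 0.11 and 0.19 with the length slope as a covariate.

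With hairpin 2, 4712 genes were higher and 4862 lower (74.4% of those tested), of which 1891 and 1658 changed at least 2-fold. The share of higher genes was 49.2%, and 71.7% with limma on log2(TPM + 1), where all genes shifted by a median of 0.33 and 2694 genes were lower.

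Hairpin 3 was compared with the control line in the same way. Log2 fold changes were -5.20 ± 0.24 for INHBE, -4.71 ± 0.14 for TRIB3 and -4.69 ± 0.53 for KLHDC7B, 3 of the largest falls. ROBO4 gave 1 read against 99 in the controls, a ratio of control to hairpin 3 of 94.7 (16.6 to 3777). EIF3CL fell by 5.42 ± 1.04, which is uncertain because it is nearly identical to EIF3C. DNAAF1 (3.90 ± 0.40), SCG2 (3.02 ± 0.17), SAMD11 (3.00 ± 0.26) and MEF2C (2.84 ± 0.30) were among the largest rises.

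The ATF4 list was lower with hairpin 3 (29 of 31 lower and 0 higher, 29 and 1 over the list alone; median -1.54; camera adjusted p = 1.42e-20, and 0.0221 with an estimated correlation), with ASNS at -2.80 ± 0.07 and SESN2 at -3.10 ± 0.09. NF-kB genes were lower in 17 of 26 cases and higher in 1 (18 and 1 over the list alone), with a median of -0.71 (camera adjusted p = 1.97e-06, and 0.0221 with an estimated correlation). LIF was at -1.73 ± 0.05, CXCL3 at -1.78 ± 0.08 and the adhesion gene ICAM1 at -1.13 ± 0.06. Heat shock genes were higher in 15 of 19 cases and lower in 1 (16 and 1 over the list alone, median 0.56, camera adjusted p = 1.97e-06), which was lost with an estimated correlation (adjusted p = 0.077). The chaperone genes HSPA1A, HSPA8, HSPH1 and DNAJA1 rose by 1.98 ± 0.12, 1.37 ± 0.06, 1.15 ± 0.09 and 1.09 ± 0.05. Of 25 cholesterol genes 13 were higher and 2 lower (13 and 3 over the list alone, median 0.29, adjusted p = 0.077 with an estimated correlation), with INSIG1 at 1.18 ± 0.06 and HMGCS1 at 1.17 ± 0.11. Histone genes (9 of 16 higher, 13 over the list alone, median 0.68, adjusted p = 0.077 with an estimated correlation) and interferon response genes (23 of 51 higher and 6 lower, also over the list alone, median 0.35, adjusted p = 0.12 with an estimated correlation) were higher under the preset correlation only. The same held for G2/M genes (21 of 43 higher and 3 lower, also over the list alone, median 0.34, adjusted p = 0.194 with an estimated correlation), with CCNA2, cyclin A2, at 0.85 ± 0.08 and KIF20A at 0.77 ± 0.07. FOXM1, a transcription factor gene of that list, fell by 0.61 ± 0.07. The call of the G2/M list was lost with length and GC offsets (0.22).

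Lower lists with hairpin 3 under the preset correlation only were the anti-apoptotic genes (5 of 10 lower, also over the list alone, median -0.35, adjusted p = 0.194 with an estimated correlation), with BCL2A1 at -2.48 ± 0.15, and the matrix genes (12 of 30 lower and 4 higher, 13 and 4 over the list alone, median -0.17, adjusted p = 0.192 with an estimated correlation), with LAMB3 at -2.80 ± 0.12. Without the first control library, the interferon (0.38), cholesterol (0.20), anti-apoptotic (-0.22) and matrix (-0.14) calls were lost, and the anti-apoptotic call also without the second (-0.31) or the third (-0.29) hairpin 3 library.

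With hairpin 3, 3036 genes were higher and 3086 lower (47.6% of those tested), of which 420 and 497 changed at least 2-fold. The share of higher genes was 49.6%, and 60.9% with limma on log2(TPM + 1), where all genes shifted by a median of 0.12. A fit of only the control and hairpin 3 libraries called 1590 genes higher and 1868 lower.

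**Figure D3:**
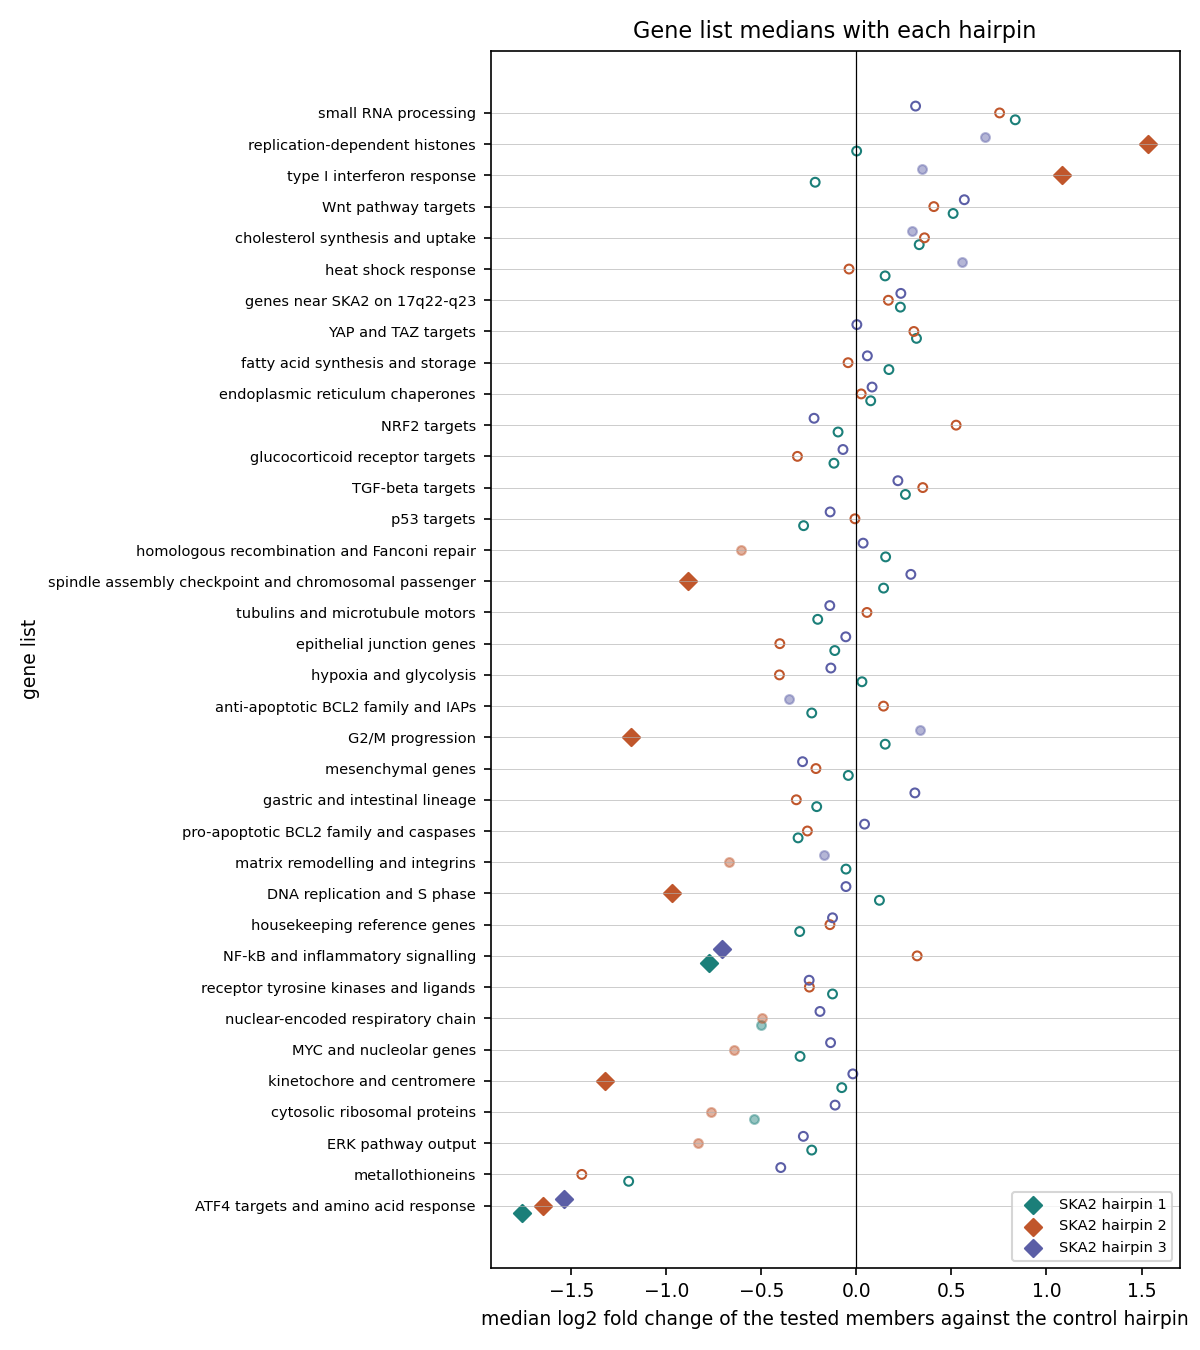
Median log2 fold change against the control hairpin (horizontal axis) of the tested members of each of the 36 gene lists (vertical axis), by SKA2 hairpin. Diamonds mark lists that camera called also with an estimated correlation, faint filled dots lists called only with the preset correlation, and open circles lists not called; the ATF4 list lies at -1.76, -1.65 and -1.54.

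Whether the hairpins differed from each other was tested directly. Hairpin 2 lowered genes of cell division against hairpin 1. All 43 G2/M genes and all 45 DNA replication genes were lower with hairpin 2 than with hairpin 1, also over the list alone, with median differences of -1.27 and -1.04 (camera adjusted p = 2.62e-18 and 1.88e-18, and 0.00744 and 0.000219 with an estimated correlation). RRM2, a ribonucleotide reductase subunit gene, differed by -2.20 ± 0.10, E2F2 by -2.12 ± 0.10, NUSAP1 by -1.68 ± 0.07 and GTSE1 by -1.42 ± 0.06. Kinetochore genes (30 of 33 lower and 1 higher, median -1.06) and spindle checkpoint genes (17 of 19 lower, median -1.04) were lower too, in the same numbers over the list alone (camera adjusted p = 9.21e-12 and 1.35e-07, and 0.000661 and 0.00788 with an estimated correlation). NDC80, the microtubule-binding subunit of the kinetochore, differed by -1.69 ± 0.07, SKA3 by -1.82 ± 0.07 and SKA1 by -1.15 ± 0.07. Interferon response (42 of 51, 43 over the list alone, median 1.13), NF-kB (21 of 26 and 1 lower, 22 and 2 over the list alone, median 0.81) and histone genes (12 of 16, 14 over the list alone, median 1.73) were higher with hairpin 2. Their camera adjusted p were 2.04e-12, 1.34e-06 and 5.33e-06, and 0.00126, 0.00788 and 0.00924 with an estimated correlation. IFI44 differed by 3.04 ± 0.19, HLA-B by 2.01 ± 0.12, the tumour necrosis factor family gene LTB by 3.08 ± 0.16 and TRAF1 by 2.40 ± 0.11.

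Single genes differed by more between hairpins 2 and 1. SERPINB7, a protease inhibitor gene, gave 288 reads against 3, a ratio of 97.5 (33.0 to 475), UBD, a ubiquitin-like modifier gene, 223 against 3, a ratio of 75.5 (25.5 to 369), CALB2 96 against 1, a ratio of 97.5 (17.1 to 3890), and MYCT1 177 against 2, a ratio of 89.9 (24.5 to 748). IGF2 gave 311 reads with hairpin 1 against 3 with hairpin 2, a ratio of 102 (34.6 to 498). The imprinted gene PEG10 differed by -3.73 ± 0.32 and STRA6, the receptor gene of retinol binding protein, by -3.57 ± 0.31. P2RY11, uncertain as above, was at least 260.5-fold lower. Altogether 3631 genes were higher and 3782 lower with hairpin 2 than with hairpin 1 (57.6% of those tested).

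Hairpin 3 differed from hairpin 2 in the opposite direction along these 7 lists, 6 of which were called also with an estimated correlation. All 43 G2/M genes (median 1.44), 43 of 45 DNA replication genes (44 over the list alone, median 1.06), 29 of 33 kinetochore genes (31 over the list alone, 1 lower, median 1.14) and 17 of 19 spindle checkpoint genes (median 1.15) were higher with hairpin 3. Camera gave adjusted p of 1.29e-17, 1.17e-15, 1.5e-11 and 9.89e-08, and 0.00791, 0.000434, 0.00068 and 0.00791 with an estimated correlation. Interferon (35 of 51 lower and 3 higher, 36 and 3 over the list alone, median -0.64) and NF-kB genes (20 of 26 lower and 3 higher, also over the list alone, median -0.82) were lower, with camera adjusted p of 1.03e-06 and 0.000167, and 0.00791 and 0.0296 with an estimated correlation. Histone genes were lower with the preset correlation only (9 of 16 lower, also over the list alone, median -0.92, camera adjusted p = 0.00569, and 0.101 with an estimated correlation). CHST11, a chondroitin sulfotransferase gene, differed by -4.74 ± 0.28 and SERPINB7 by -4.99 ± 0.49. RCN3, a calcium-binding protein gene of the endoplasmic reticulum, differed by 3.68 ± 0.46 and MCAM by 3.54 ± 1.26. CALB2 gave 96 reads with hairpin 2 against 2 with hairpin 3, a ratio of 50.1 (13.5 to 420), and IGF2 194 reads with hairpin 3 against 3 with hairpin 2, a ratio of 62.0 (20.9 to 303). P2RY11 was at least 241-fold higher with hairpin 3 and PHOSPHO2-KLHL23 at least 76.1-fold lower, both uncertain as above. The call of MCAM was lost in limma-voom (2.94), with limma on log2(TPM + 1) (0.74), with the length slope as a covariate (0.26), and without any 1 of the hairpin 2 libraries (3.31 to 3.73) or the third hairpin 3 library (2.33). In total 4295 genes were higher and 4105 lower with hairpin 3, 51.1% of the calls higher, against 30.3% with limma on log2(TPM + 1), where all genes shifted by a median of -0.22.

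Hairpins 3 and 1 differed least. The immediate-early transcription factor genes FOS, NR4A1 and FOSB were higher with hairpin 3 by 3.96 ± 0.09, 1.79 ± 0.09 and 1.69 ± 0.09, and the gastric mucin gene MUC6 by 2.56 ± 0.38. FOS was at 28.7 CPM in the controls and at 6.65, 56.7 and 104 CPM with hairpins 1, 2 and 3. SLCO1C1 (-2.05 ± 0.46), MSRB3, a methionine sulfoxide reductase gene (-1.60 ± 0.32), and PKDREJ (-1.54 ± 0.22) were lower with hairpin 3, as was POTEE (-1.86 ± 0.47), which is uncertain because it is nearly identical to POTEF. Higher lists that held with an estimated correlation were the p53 targets (9 of 29, 12 over the list alone, median 0.24), interferon response (12 of 51, 17 over the list alone, 0.38), heat shock (11 of 19, 13 over the list alone, 0.32) and histone genes (7 of 16, 10 over the list alone, 0.67). Their camera adjusted p were 7.03e-06, 4.99e-09, 3.14e-09 and 6.04e-06, and 0.0198, 0.0118, 0.0354 and 0.0198 with an estimated correlation, and the histone call was lost with length and GC offsets (0.24). In total 611 genes were higher and 605 lower with hairpin 3 (9.45% of those tested), with 50.2% of the calls higher against 15.4% with limma on log2(TPM + 1), where all genes shifted by a median of -0.19. Every library left out, except the third control library, moved these counts by more than 1.5 times. They were 2536 and 2731 without the first hairpin 3 library, 1339 and 1291 without the first control library, and 333 and 357 without the second. Without 1 of the hairpin 1 libraries they lay between 100 and 136 and between 139 and 162, without 1 of the hairpin 2 libraries between 330 and 380 and between 336 and 380, and without the second or the third hairpin 3 library at 120 and 135 or 118 and 157. The calls of SLCO1C1 (-2.05) and POTEE (-1.87) were lost in a fit of only these groups, without any 1 of the hairpin 1 libraries (-2.15 to -1.96 and -1.99 to -1.75) and without the second (-1.80 and -1.57) or the third hairpin 3 library (-1.69 and -1.49), and that of POTEE also without any 1 of the hairpin 2 libraries (-1.86 to -1.85). The call of MSRB3 was lost without the second (-1.47) or the third hairpin 1 library (-1.59) and without the second (-1.41) or the third hairpin 3 library (-1.37).

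Transcript length went with the direction of change. Genes called higher in the mean of the hairpins had a median effective length of 4176 bases and those called lower 1902 bases, with a median GC content of 43.4% and 55.7%. Ribosomal protein and respiratory chain genes, which have short transcripts, were among the lower ones. Across genes, the log2 fold change correlated with effective length at a Spearman rho of 0.534, 0.473 and 0.322 for hairpins 1, 2 and 3. The length slope of a library, its log2 CPM against the mean of all libraries per doubling of length, was -0.0556, -0.238 and -0.317 in the control libraries. It was 0.0942 ± 0.0121 with hairpin 1, 0.175 ± 0.0255 with hairpin 2 and -0.0658 ± 0.138 with hairpin 3 (SD, n = 3), where the first library stood apart at 0.0910. The knockdown mean exceeded the control mean by 0.271, and an exact two-sided permutation test over 220 splits gave p = 0.0136. That test treats the libraries as exchangeable, although they come from 4 lines. With the lines kept whole, no share below 0.25 is possible. The 3 control libraries alone spanned 0.261. Within the numbers read as possible pairs of control and hairpin 3 libraries, hairpin 3 exceeded the control by 0.147, 0.117 and 0.149. With length and GC offsets, between 66.8% and 83.8% of the genes called against the control were called again in the same direction, and with the length slope as a covariate between 40.8% and 92.6%. Others were called in the reverse direction. With offsets these were 277 of the higher and 334 of the lower genes for hairpin 2, 237 and 308 for the mean, 155 and 152 for hairpin 1 and 0 and 4 for hairpin 3, and with the covariate 243 and 218, 164 and 163, 87 and 125, and 0 and 0.

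**Figure D4:**
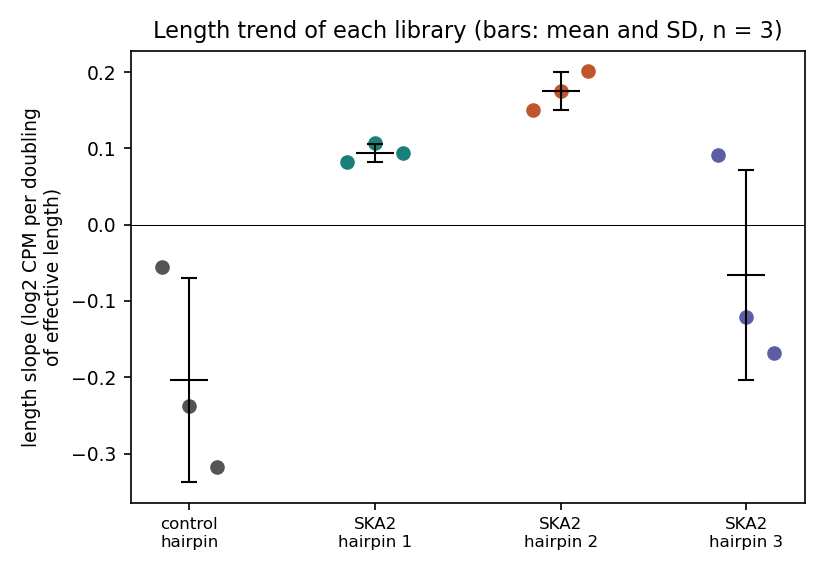
Length slope of each of the 12 libraries (points; log2 CPM per doubling of effective length, relative to the mean of all libraries) by line, with bars for the mean and SD (n = 3) and a line at 0. The control libraries lie between -0.317 and -0.0556, and 7 of the 9 knockdown libraries lie above all 3 of them.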

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

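The tests of the SKA2 level and of an off-target effect for hairpin 2, both tests of the length slope and the counts with lines kept whole were chosen after the results they measure had been seen, and the length and GC offsets and the length slope as a covariate were added after the data had been seen. What singled out each result of the next paragraph is a tested difference between hairpins that were all compared with the same control line. Of the patterns weighed after it, only the second is such a difference.

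Between hairpins 2 and 1, 3631 genes were higher and 3782 lower with hairpin 2. SKA1 differed by -1.15, SKA3 by -1.82 and PRR11 by -0.53 on the log2 scale. The median differences were -1.06 for kinetochore, -1.04 for spindle checkpoint, -1.27 for G2/M and -1.04 for DNA replication genes, and 1.13 for interferon, 0.81 for NF-kB and 1.73 for histone genes. Between hairpins 3 and 2, 4295 genes were higher and 4105 lower with hairpin 3, with SKA1 at 1.38, SKA3 at 2.04 and PRR11 at 0.58, and with medians of 1.14 for kinetochore, 1.15 for spindle checkpoint, 1.44 for G2/M, 1.06 for DNA replication, -0.64 for interferon and -0.82 for NF-kB genes. Between hairpins 3 and 1, 611 genes were higher and 605 lower with hairpin 3, and the medians were 0.24 for p53 targets, 0.38 for interferon, 0.32 for heat shock and 0.67 for histone genes. These 611 and 605 genes became 2536 and 2731 without the first hairpin 3 library, 1339 and 1291 without the first control library, 333 and 357 without the second, and 100 and 139 without the second hairpin 1 library.

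The first pattern is the fall of ATF4 and amino acid response genes with all 3 hairpins. A transcript length and GC trend as the whole cause is argued against by the offsets, under which the median nearest to 0 among the hairpins was -1.52. A state of the libraries along the length trend is argued against as well, since the median of the mean contrast was -1.38 with the length slope as a covariate. What stays open is the state of the control line, because the design has 1 control line and an ATF4 response that was on in that line may look like a fall in the others. A response to lower SKA2 remains a hypothesis that cannot be told apart from it.

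The second pattern is the lower level of G2/M genes with hairpin 2 than with hairpin 1. The median difference was -1.30 with length and GC offsets, which argues against that trend as the whole cause. A deeper knockdown of SKA2 RNA is argued against as well, since its log2 difference between hairpins 2 and 1 was 0.075. The SKA2 protein was not measured here, so its loss could not be compared between hairpins. An off-target effect of hairpin 2 stays open. Hairpins 1 and 3, with SKA2 RNA at a similar level, did not lower the list (the lower of their medians was 0.15). The hairpin sequences were not used here, however, so their predicted targets could not be examined.

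The third pattern is the higher level of long transcripts in knockdown libraries. The slopes within the control line spanned 96.4% of the difference between the knockdown and control means, and 7 of the 9 knockdown libraries lay above all 3 control libraries. Within the numbers read as possible pairs of control and hairpin 3 libraries, however, hairpin 3 was higher in all 3 pairs, by 0.147, 0.117 and 0.149. The remaining libraries thus also lay above the same-numbered controls. No label gives this pairing, which was read from deviations of these same libraries, so the pairs are not independent support. With 3 pairs an exact two-sided sign-flip test cannot give a p below 0.25. A trend that differs from library to library and SKA2 knockdown itself both stay open and cannot be told apart.

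Other splits of the libraries were counted for each comparison. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison only 1, the real one, gave as many genes. The real split called 7754 genes for hairpin 1 against the control (highest other 0), 9256 for hairpin 2 (0), 3458 for hairpin 3 (1), 9606 between hairpins 2 and 1 (0), 336 between hairpins 3 and 1 (0) and 7937 between hairpins 3 and 2 (1). The numbers of the control and hairpin 3 libraries were read as possible pairs. Their other splits included those that part every such pair, as the real one does, and these called 0 genes. Of 100 regroupings of the 12 libraries only 1, the real one, gave as many genes for the mean of the hairpins (8947, highest other 653) and for genes called with all 3 hairpins (3718, highest other 7). This bears only on the assignment of single libraries, and not on chance differences between lines. The highest values were the same among the 53 regroupings that part all 3 pairs of control and hairpin 3 libraries, as the real one does. These regroupings mix the lines, which widens the spread within groups, and 95 of the 99 others called 0 genes for the mean. With the lines kept whole there are only 4 arrangements, too few for a share under 0.05. Hairpin 2 in the place of the control gave more genes than the real arrangement (9216 for the mean and 5151 shared), hairpin 1 gave 5077 and 279 and hairpin 3 4514 and 274. A difference between lines that is not due to SKA2 is therefore not excluded by these counts.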

How the results depend on the processing

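The length and GC offsets, the length slope as a covariate and the tests without the first control and first hairpin 3 libraries were chosen after the data had been seen. Counts are given as higher and lower. A change of at least 2-fold left 909 and 606 genes for hairpin 1, 1891 and 1658 for hairpin 2, 420 and 497 for hairpin 3, 871 and 684 for the mean, 846 and 959 between hairpins 2 and 1, 37 and 45 between hairpins 3 and 1, 1046 and 1175 between hairpins 3 and 2, and 247 and 268 shared by all 3, by its own construction. At an adjusted p under 0.01, 1831 genes were higher for hairpin 3, 102 and 135 differed between hairpins 3 and 1, and 981 and 1235 were shared. DESeq2 gave 1071 higher genes between hairpins 3 and 1. With limma on log2(TPM + 1) the counts were 6462 and 1733 for hairpin 1, 2694 lower for hairpin 2, 6696 and 2321 for the mean, 242 and 1332 between hairpins 3 and 1, 2469 higher between hairpins 3 and 2, and 888 shared lower. Fits of only the groups compared gave 1590 and 1868 for hairpin 3, 144 and 192 between hairpins 3 and 1, and 948 and 1242 shared. They have fewer libraries, but a fit of the hairpin 2 and hairpin 1 libraries alone called 9606 genes, against 7413 in the full fit. For the mean, the fit that took the 9 knockdown libraries as 1 group held all 12 libraries, counted differences between hairpins as spread and gave 2518 and 2408. With offsets 1704 and 1455 genes differed between hairpins 3 and 1. With the length slope as a covariate the counts were 2522 higher for hairpin 1, 1818 and 1708 between hairpins 3 and 1, and 1154 shared higher. Without the first control and first hairpin 3 libraries 3664 and 3751 differed between hairpins 3 and 1.

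An estimated correlation in camera left 2 lower lists for hairpin 1, 5 for hairpin 2, 0 higher and 2 lower for hairpin 3, and 0 higher and 3 lower for the mean. Fry, which does not compare a list with other genes, called 11 and 19 lists for hairpin 1, 11 and 21 for hairpin 2, 11 and 13 for hairpin 3, and 10 and 21 for the mean. With offsets 7 and 7 lists were called for hairpin 1 and 4 higher for hairpin 2. With the length slope as a covariate these were 5 and 7 for hairpin 1, 5 higher for hairpin 2 and 7 higher for the mean, and the medians of the respiratory list turned to 0.052 (hairpin 1), 0.19 (hairpin 2), 0.10 (mean) and -0.10 (hairpins 3 and 2), and those of the ribosomal list to 0.12, 0.11 and 0.15. Except for the 2-fold change, the cause of these moves was not tested.

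Leaving out 1 library at a time gave 3339 to 4502 higher and 3395 to 4506 lower genes for hairpin 1, 4341 to 4958 and 4522 to 5072 for hairpin 2, 2163 to 3793 and 2482 to 3619 for hairpin 3, and 3574 to 4658 and 3927 to 4769 for the mean. The ranges were 3207 to 4176 and 3215 to 4127 between hairpins 2 and 1, 3729 to 4552 and 3649 to 4537 between hairpins 3 and 2, and 1404 to 2523 shared lower. Larger moves were those between hairpins 3 and 1, 100 (without the second hairpin 1 library) to 2536 (without the first hairpin 3 library) higher and 135 (without the second hairpin 3 library) to 2731 (without the first) lower, and shared higher genes, 1147 without the third control library, 1190 without the second, to 2547. Lists called higher ranged from 0 to 2 for hairpin 1 (2 without the third control library), 3 to 6 for hairpin 3 (3 without the first control library) and 2 to 5 for the mean (2 without the first control library). SKA2 stayed between -2.39 and -2.13 for the 3 hairpins.

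With the replicate number as a block, 4138 and 4066 genes were called for hairpin 1, 4768 and 4867 for hairpin 2, 3149 and 3152 for hairpin 3, 4387 and 4610 for the mean, and 628 and 723 between hairpins 3 and 1, so that the block moved none of these counts by more than 1.5 times. The block gives all lines the same replicate effects, so a pairing of only the control and hairpin 3 libraries was not modelled. Of 252 list values with the block, 249 kept their side of the threshold, spindle checkpoint genes between hairpins 3 and 1 lost the call, and small RNA processing genes gained it for the mean and between hairpins 3 and 1. Over all same-numbered libraries, 5 of 12 correlated best with a library of their own number.

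Among named genes, 2127 of 2169 values over 26 alternatives kept their direction and side of the threshold, 39 lost the call, 3 gained it and 0 reversed. Apart from SKA2, SKA1, SKA3 and PRR11, these genes were picked for large calls in the main fit, so these values say little about other genes. The stricter filter gave values for only 46 of the 85 results. Of 252 list values, 252 kept theirs with RLE scaling, 248 with library size alone, 206 with offsets, 211 with the length slope as a covariate and 228 without the first control and first hairpin 3 libraries. Depth limits genes with 0 to 3 counts in a group, for which only a floor or a wide interval can be given.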

Other observations

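The tests of HOX and immediate-early genes were chosen after their values had been seen, and they are descriptions without a test of the group. Of 10 tested genes of the HOXA cluster, which encodes homeobox factors of body patterning, 9, 7 and 10 were higher and 0 lower with hairpins 1, 2 and 3, with medians of 1.57, 1.04 and 1.51 on the log2 scale. The log2 fold changes of HOXA13 were 2.46, 2.16 and 2.43, and those of HOXA10 1.55, 1.20 and 1.66. HOXA5, HOXA2 and HOXA9 were not called with hairpin 2, at -0.066, -0.36 and 0.29 (adjusted p = 0.577, 0.146 and 0.0861 in edgeR), and were at 2.21, 0.57 and 0.61 with hairpin 1 and 1.93, 0.65 and 0.73 with hairpin 3. Of 9 HOXB genes 0 were higher and 5 lower with each hairpin (medians -0.41, -0.68 and -0.41), and the medians of 8 HOXC genes were -0.30, -0.18 and 0.01. With length and GC offsets the mean over the hairpins had a median of 1.51 for HOXA and of -0.15 for HOXB genes.

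Of 18 tested immediate-early genes, which respond within minutes to growth factors and stress, 14 were lower and 3 higher with hairpin 1 (median -1.01), 5 lower and 10 higher with hairpin 2 (0.32), and 6 lower and 7 higher with hairpin 3 (0.24). Tested directly, 16 were higher with hairpin 2 and 14 with hairpin 3 than with hairpin 1 (medians 1.12 and 0.85). EGR1 was at -1.66, -0.76 and -0.21 and ATF3 at -2.11, -0.51 and -0.75.

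Several lists were not called by camera for any hairpin against the control, and their medians follow in the order of hairpins 1, 2 and 3. Small RNA processing genes came to 0.84, 0.75 and 0.31 (adjusted p = 0.078, 0.0649 and 0.252), with 8, 9 and 4 of 13 higher, also adjusted over the list alone, and DICER1, which cuts microRNA precursors, at 1.54 ± 0.26, 1.91 ± 0.26 and 1.05 ± 0.26. Metallothioneins came to -1.20, -1.44 and -0.40 (adjusted p = 0.078, 0.0649 and 0.527), with 4, 5 and 1 of 5 lower, also over the list alone. Medians were -0.28, -0.01 and -0.14 for p53 targets, 0.51, 0.41 and 0.57 for Wnt targets, 0.32, 0.30 and 0.00 for YAP and TAZ targets, 0.26, 0.35 and 0.22 for TGF-beta targets, and -0.10, 0.52 and -0.22 for NRF2 targets. They were -0.11, -0.40 and -0.06 for epithelial junction genes, -0.04, -0.21 and -0.28 for mesenchymal genes, -0.21, -0.32 and 0.31 for gastric and intestinal lineage genes, -0.12, -0.31 and -0.07 for glucocorticoid targets, and -0.13, -0.25 and -0.25 for receptor tyrosine kinases. Some of these lists gained a call without 1 library. This held for gastric and intestinal genes with hairpin 3 without its first library (0.52), for metallothioneins with hairpins 1 and 2 (-1.40 and -1.60) and small RNA processing genes with hairpin 2 (0.97) without the first control library, and for p53 targets with hairpin 1 without the second or the third control library or the first or the third hairpin 1 library (-0.30 to -0.23). For receptor tyrosine kinases it held with hairpin 2 without the third hairpin 2 library (-0.29), and with hairpin 3 without the second or the third control library, the second hairpin 1 library, the first or the third hairpin 2 library or the first hairpin 3 library (-0.26 to -0.20). Hypoxia genes were at 0.03, -0.40 and -0.13, fatty acid genes at 0.17, -0.04 and 0.06, endoplasmic reticulum chaperones at 0.08, 0.03 and 0.08, tubulins and motors at -0.20, 0.06 and -0.14, pro-apoptotic genes at -0.31, -0.26 and 0.04, and housekeeping genes at -0.30, -0.14 and -0.13.

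Between hairpins, more lists were called with the preset correlation and not with an estimated one. For hairpin 2 against hairpin 1 these were recombination (-0.56, adjusted p = 0.224 with an estimated correlation), p53 (0.51, 0.0671), chaperone (0.34, 0.0886), hypoxia (-0.35, 0.204), ribosomal (-0.21, 0.918), ERK (-0.61, 0.224), MYC (-0.34, 0.204) and matrix genes (-0.53, 0.0902). The ribosomal call was also lost without the third hairpin 2 library (-0.15). For hairpin 3 against hairpin 1 they included ribosomal (0.43, adjusted p = 0.439 with an estimated correlation), respiratory (0.35, 0.439), G2/M (0.18, 0.167) and metallothionein genes (0.80, 0.229), and for hairpin 3 against hairpin 2 ribosomal (0.66, 0.548), MYC (0.46, 0.153) and heat shock genes (0.42, 0.268). Lower medians with hairpin 3 than with hairpin 1 were those of DNA replication (-0.088), hypoxia (-0.13) and fatty acid genes (-0.14). These calls were also lost without the first hairpin 3 library.

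Markers of other cell types had too few tested members for a test. The summed level of fibroblast markers (4 of 10 tested) was 46.4 to 51.6 CPM in the control and 19.7 to 29.5 CPM in the knockdown libraries, and that of endothelial markers (2 of 9 tested) 35.5 to 50.4 and 14.4 to 34.3 CPM. For both, all 9 knockdown libraries lay below all 3 control libraries, where chance gives no overlap in 0.909% of splits. That share treats the libraries as exchangeable, although they come from 4 lines. With the lines kept whole, no share below 0.25 is possible. The markers with the highest levels were ACTA2, or COL1A1 in 1 hairpin 2 library, and EGFL7. Immune markers (2 of 11 tested) were at 11.5 to 26.8 CPM and embryonic kidney cell markers (4 of 8 tested) at 15.3 to 30.1 CPM, with control and knockdown libraries overlapping. Hairpin 2 libraries were the lowest in each of these lists. The mitochondrial genome list had 0 members in the table.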
